A study of Mus musculus with 6 samples.

How the data were processed

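RNA was measured on 6 arrays from mouse cumulus-oocyte complexes (COCs), the immature oocytes of antral follicles with the somatic cumulus cells that enclose them. Per the labels' protocols, wildtype females were primed with 5 IU of equine chorionic gonadotropin (eCG) for 46 h, and groups of 100 COCs were cultured with the vehicle DMSO or with 5 µM Torin1, an ATP-competitive inhibitor of the kinase MTOR. The labels give the age of the mice as 21 days in one place and 23 days in another, and the culture time as 14 h in the sample source and 16 h in the growth protocol; which of the 2 times applies was not settled. The medium held 3 mg/ml of serum albumin and 5 µM milrinone, an inhibitor of the oocyte phosphodiesterase PDE3 that keeps oocytes from resuming meiosis. Total RNA was amplified as cDNA with the NuGEN Ovation Pico WTA system and labelled with biotin, per the labels' protocols. Samples were grouped by their titles into 3 DMSO and 3 Torin1 samples. The labels call them separate sets but do not say whether these came from separate mice or culture days, so p-values measure only the spread between these samples, which may be technical. The description of Torin1 sample 3 gives it the same short name as sample 2, so treating both as 1 sample was run as an alternative.

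The deposited intensities are 1 value per probe set and array, made with GCOS, Affymetrix Expression Console 1.1 and RMA, per the submitters' processing notes. Settings and order of these steps, and the build of the array's probe sets, are not given in the sources used here. RMA corrects background, applies quantile normalization to probes and summarises each probe set by median polish. A common distribution is thereby imposed on the arrays, so a change is relative to the other transcripts on the array. The values lie on a linear scale, from 2.25 to 3268 with array medians of 11.1 to 11.97, while the design fixed before the data were examined assumed log2 values. The planned fallback was therefore used: log2(intensity + 1), on which a fold change understates the change of dim genes. No per-probe background was used here, and the number of arrays limits the precision.

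Of 41345 probe sets, 25335 were in the platform's gene table. Of these, 23521 named 1 gene and 1814 named several, while 16010 were unnamed here. Entrez identifiers of 23328 probe sets matched the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. Probe sets naming 1 gene gave 22180 genes. For the 1082 genes with several probe sets, the probe set with the highest mean over all arrays was kept. Probe sets naming several genes were left out of the tests and counted separately. Near-identical copies, as among ribosomal proteins and oocyte gene families such as Oog, Obox, Khdc1 and Tcl1b, can share signal, so values of their members are uncertain. Coordinates were not used here.

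Torin1 was compared with DMSO by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate, no filter on dim genes), with Benjamini-Hochberg adjustment over all genes and a call at an adjusted p below 0.05. Every adjusted p of a gene comes from this fit. Fold changes are given as log2 Torin1 minus DMSO with their standard error (SE). Before the data were examined, 35 gene lists were fixed, with 1001 entries of which 905 were measured. The erythroid list had under 5 measured members, and the other 34 were tested by camera of limma with its preset inter-gene correlation of 0.01, adjusted over the lists. Camera with the correlation estimated for each list, and fry, were run beside it. Some lists overlap; for example, the markers raised by the oocyte share Fdps and Mvk with cholesterol biosynthesis and Pfkp with glycolysis. A list's median was also set against 10000 random lists matched on mean level in 20 bins. Exact permutation of 3 against 3 cannot go below p = 0.1, so no such test was used for genes.

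Named genes followed a rule fixed before the data were examined. It took the 12 largest called rises and the 12 largest called falls with no overlap between groups and a mean above the median gene in the higher group, up to 4 called members of each list with the largest change (2 with the smallest p where none was called), and a fixed set given whatever its outcome. Predicted, accession-like, small RNA, olfactory and vomeronasal genes were left out of the first part. Of the fixed set, Lhcgr and Cyp19a1 are not analysed here, because no probe set named them alone. Further genes, chosen after their values were seen, complete counts of 5 or fewer or serve as examples: Egfr, Ptger2, Nr0b1, Hsd17b1, Esr2, Foxl2, Slc38a1, Cbs, Aldh18a1, Kars, Sars, Skil, Smad9, Cnn1, Pfkm, Klf9, Irs1, Foxo1, Lamtor2, Mapkap1, Sqstm1, Gabarapl2, Ctsb, Tfe3, Star, Mdm2, Cdkn1a, Plk4, Syvn1, Ern1, Ppp1r15a and Sel1l.

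The fit was tested on simulated data with the 22180 genes of this comparison. Of 50 genes changed by each size, 26% were recovered at an absolute log2 change of 0.5, 76% at 1, 92% at 2 and 100% at 3, and 3.92% of calls were false. Noise was drawn independently for each gene and array, with no array set apart, so these rates need not hold for the real arrays. Camera called 2 of 100 simulated unchanged lists at p below 0.05; those genes were drawn independently, so correlation among real genes was not covered. Alternatives were another quantile normalization, centring arrays on their median or 75th percentile, leaving out genes below the median level, averaging probe sets, eBayes with a trend or robust, array weights, the sample number as a block, Torin1 samples 2 and 3 as 1 sample, each array left out in turn, an adjusted p below 0.01, and a pseudocount of 16. Taking log2 with no pseudocount was added after the data were seen.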

Results

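COCs cultured with DMSO or Torin1 were profiled to ask which transcripts change in the complex with this MTOR inhibitor. The activity of MTOR itself was not measured on the arrays. The data comprise 3 DMSO and 3 Torin1 arrays with 41345 probe sets each, and array medians ran from 11.1 to 11.97 intensity units. The first principal component took 67.2% of the variance and separated the groups, with scores of -33.1 to -31.2 for DMSO and 29.9 to 37.1 for Torin1. The second took 16.5% and set Torin1 sample 3, at 30.4, apart from Torin1 samples 1 and 2, at -14.1 and -19.8. Over genes, log2 differences between replicates had an SD of 0.212 to 0.240 among DMSO samples. The corresponding SD was 0.204 between Torin1 samples 1 and 2, but 0.327 and 0.350 between these and Torin1 sample 3.

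**Figure D1:**
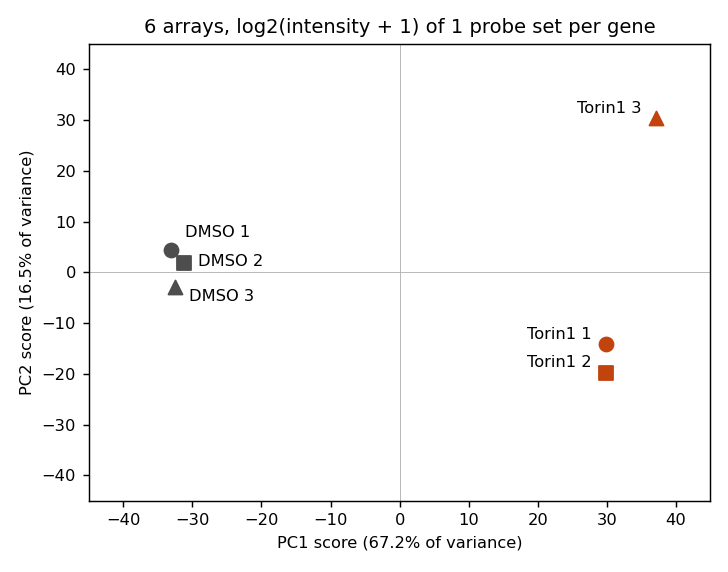
Scores of the 6 arrays on the first (x axis, 67.2% of variance) and second (y axis, 16.5%) principal components of log2(intensity + 1), with colour for treatment and symbol for sample number. DMSO and Torin1 arrays lie on opposite sides of the x axis, and Torin1 sample 3 lies at 30.4 on the y axis.

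Torin1 changed 2678 of 22180 genes, with 1138 higher and 1540 lower, and no called gene had overlapping values between the groups. At least 2-fold changes numbered 808, of which 345 were rises and 463 were falls. Ptgs2, the inducible synthase of the prostaglandin pathway, rose from 4.16 ± 1.01 to 9.60 ± 0.16 on the log2 scale (SD, n = 3 each). Its DMSO level lay at that of the median gene, 4.17, so the size of this rise is uncertain. Hpgd, which degrades prostaglandins, fell by 3.95 ± 0.22 (SE). The anti-Müllerian hormone receptor gene Amhr2 fell from 8.03 ± 0.14 to 4.04 ± 0.95 (SD, n = 3 each).

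The other leading rises lay between 4.05 and 4.75. They were Gpr83, Tnfaip6, Nts (neurotensin), Il23a (a cytokine subunit), Egr3, Btc, Osgin2, Creb3l1, Sult1e1 (an estrogen sulfotransferase), Plaur (the urokinase receptor) and Ptprn. Their adjusted p ran from 3.4e-05 for Osgin2 to 0.000612 for Plaur. Of these, Sult1e1, Nts, Plaur, Btc and Egr3 started from DMSO means of 2.75, 2.97, 3.58, 3.81 and 3.89. Those levels lay below the median gene (4.17), so the size of these rises is uncertain as well. The other leading falls lay between -3.91 and -3.13 and had adjusted p from 5.3e-05 for Smpdl3b to 0.00617 for Kctd14. They were Atp1b2 (a sodium pump subunit), Gstm2 (a glutathione transferase), Kctd14, Slc18a2 (a vesicular monoamine transporter), Sectm1b, Slc38a5 (an amino acid transporter), Smpdl3b, Gm2a, Tmem182 and Dynap. Of these, Gstm2, Sectm1b, Kctd14 and Dynap ended at Torin1 means of 3.725, 3.48, 3.26 and 3.22, below the median gene. Amhr2 and Hpgd, at 4.04 and 4.07, also ended below it, so the size of these falls is uncertain too. Each of these 24 genes stayed called when any 1 array was left out.

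Complete separation of 3 against 3 values was seen in 28.6% of genes, where chance alone gives 10%. Leaving out DMSO 1, DMSO 2 or DMSO 3 lowered the count of changed genes from 2678 to 1730, 1763 or 1518. Without Torin1 1 the falls numbered 1021, without Torin1 2 the rises numbered 757, and without Torin1 3, the sample that stood apart, 3083 genes changed. With a pseudocount of 16, 466 genes in place of 808 changed at least 2-fold.

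Genes of cumulus expansion, the process in which cumulus cells build a hyaluronan-rich matrix around the oocyte, were mostly higher with Torin1. Of 16 measured members 11 rose, 2 fell and 3 were not called (12 higher and 2 lower when adjusted over the list alone), with a median log2 change of 2.28. Has2, a hyaluronan synthase, rose from 5.83 ± 0.34 to 9.36 ± 0.13 (SD, n = 3 each), or 11.5-fold. Tnfaip6, whose product modifies hyaluronan in that matrix, rose by 4.71 ± 0.20 (SE), and Btc, a ligand of the epidermal growth factor receptor, by 4.50 ± 0.20. The members that fell were Egfr, the receptor itself, by 1.74 ± 0.27, and Ptger2, a prostaglandin E2 receptor, by 1.02 ± 0.18. As a list they were called higher by camera (adjusted p = 2.58e-11), but not with an estimated correlation (adjusted p = 0.101). Ptger2 was not called without DMSO 3 (adjusted p = 0.0515).

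Growth factor immediate-early and ERK feedback genes were also higher. Of 28 measured members 18 rose, 0 fell and 10 were not called (21 higher when adjusted over the list alone), and the median was 1.26. The transcription factor genes Egr3 and Junb rose by 4.52 ± 0.24 and 2.75 ± 0.17. Dusp4 and Spry2, which encode negative regulators of ERK signalling, rose by 4.01 ± 0.23 and 3.12 ± 0.25. The list was called higher by camera (adjusted p = 2.21e-17) and not with an estimated correlation (adjusted p = 0.125).

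**Figure D2:**
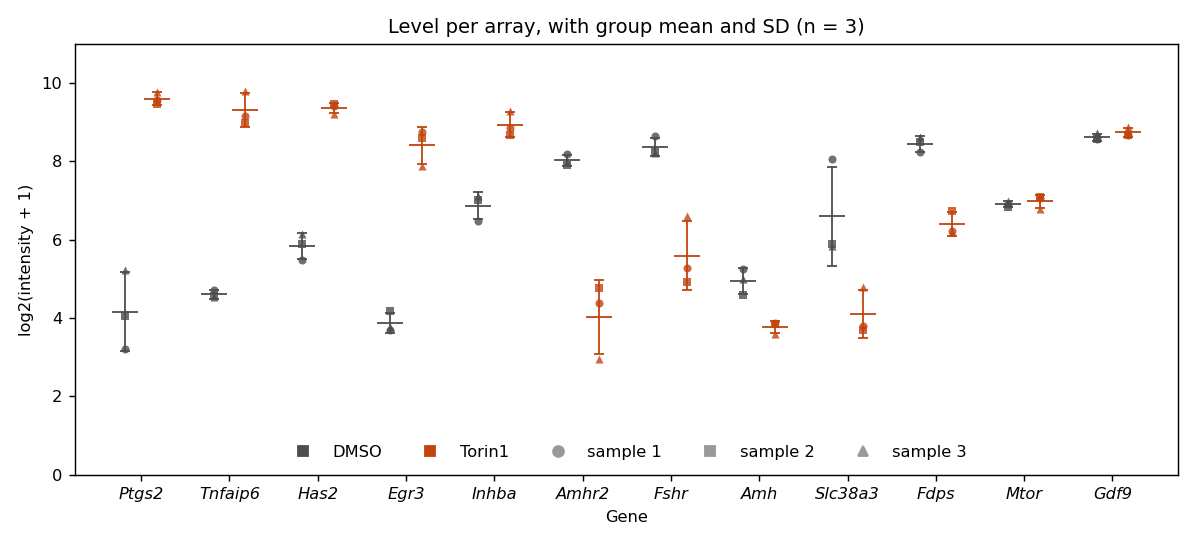
Level of 12 genes (x axis) in each array as log2(intensity + 1) (y axis), with symbols for single arrays, horizontal bars for group means and whiskers for the SD (n = 3). Ptgs2, Tnfaip6, Has2, Egr3 and Inhba were higher and Amhr2, Fshr, Amh, Slc38a3 and Fdps lower with Torin1, while Mtor (log2 change 0.07) and Gdf9 (0.12) were not called.

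Many granulosa lineage genes fell. Of 22 measured members 13 fell, 1 rose and 8 were not called (13 lower and 1 higher when adjusted over the list alone), with a median of -0.71. Fshr, the follicle-stimulating hormone receptor gene, fell by 2.78 ± 0.40, from 8.37 ± 0.24 to 5.59 ± 0.88 (SD, n = 3 each), and Tnni3 fell by 2.21 ± 0.08. Hsd17b1, Esr2 and Foxl2, which encode an estradiol-forming enzyme, an estrogen receptor and a granulosa transcription factor, also fell (-1.70 ± 0.14, -1.53 ± 0.13 and -1.47 ± 0.12). Nr0b1 rose by 0.62 ± 0.16 and was called in the full set but not without DMSO 1, DMSO 2, DMSO 3, Torin1 1 or Torin1 2 (adjusted p up to 0.152). The list was called lower by camera (adjusted p = 1.85e-07), but not with an estimated correlation (adjusted p = 0.101). Beside these falls, the median of 50 oocyte transcripts on the same arrays was 0.20 higher.

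Cumulus markers known to be raised by oocyte signals were lower as a list. Of 12 measured members 7 fell, 1 rose and 4 were not called, and the same counts held when adjusted over the list alone; the median was -0.58. Slc38a3, an amino acid transporter gene, fell from 6.60 ± 1.26 to 4.10 ± 0.61 (SD, n = 3 each), and Amh fell by 1.17 ± 0.17. Sfrp2 rose by 1.95 ± 0.46. By camera the list was lower (adjusted p = 0.000644), and with an estimated correlation it was not called (adjusted p = 0.125). Slc38a3 was not called without DMSO 2, DMSO 3, Torin1 1 or Torin1 2 (adjusted p up to 0.119), nor Sfrp2 without DMSO 1, DMSO 2, DMSO 3 or Torin1 2 (adjusted p up to 0.112).

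Mural granulosa markers went both ways and were not called as a list (adjusted p = 0.679). Among 14 members 3 rose, 2 fell and 9 were not called, also when adjusted over the list alone. Inhba, a subunit of activins and inhibins, rose by 2.06 ± 0.21, and Fdx1 and Star, which serve steroid synthesis, rose by 1.97 ± 0.12 and 0.50 ± 0.08. Star was dim, with means of 3.68 in DMSO and 4.18 in Torin1. Inhbb, another such subunit, fell by 1.85 ± 0.43 and Kitl, the kit ligand gene, by 1.52 ± 0.35. Inhbb was not called without DMSO 2, DMSO 3 or Torin1 2 (adjusted p up to 0.12), nor Kitl without DMSO 2, DMSO 3, Torin1 1 or Torin1 3 (adjusted p up to 0.111).

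Many lipid synthesis genes fell. All 20 measured cholesterol biosynthesis genes had a change below 0, with 15 called lower, 0 higher and 5 not called (17 lower when adjusted over the list alone) and a median of -0.96. Mvk and Fdps, which encode enzymes of the mevalonate pathway, fell by 2.04 ± 0.13 and 2.06 ± 0.17, and Lss, the lanosterol synthase gene, and Mvd fell by 1.77 ± 0.19 and 1.43 ± 0.21. Camera called the list lower (adjusted p = 4.16e-13), but not with an estimated correlation (adjusted p = 0.241). Of 15 fatty acid synthesis genes 6 fell, 0 rose and 9 were not called (7 lower when adjusted over the list alone), with a median of -0.42. The desaturase genes Fads2 and Fads1 fell by 2.10 ± 0.13 and 1.34 ± 0.14, and Acaca and Fasn, for the carboxylase and synthase of fatty acid synthesis, by 0.93 ± 0.12 and 0.67 ± 0.11. That list had an adjusted p of 0.000409 by camera and an adjusted p of 0.440 with an estimated correlation.

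Nuclear-encoded subunits of oxidative phosphorylation showed smaller changes, nearly all below 0. Of 56 measured genes 55 had a change below 0, 26 were called lower, 0 higher and 30 were not called (37 lower when adjusted over the list alone). The median was -0.38. Ndufs8, a complex I subunit gene, fell by 1.06 ± 0.16, and Cox6b1, a complex IV subunit gene, fell by 0.66 ± 0.08. Ndufb3 and Ndufb7, also of complex I, fell by 0.67 ± 0.10 and 0.64 ± 0.13, and Ndufb7 was not called without DMSO 1, DMSO 2, DMSO 3 or Torin1 1 (adjusted p up to 0.0842). Camera gave an adjusted p of 2.21e-17, and with an estimated correlation the list was not called (adjusted p = 0.229).

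Glycolysis and nucleotide synthesis were not called as lists. Among 20 glycolysis genes 2 rose, 3 fell and 15 were not called (2 higher and 6 lower when adjusted over the list alone), with a list adjusted p of 0.152. Hk2, a hexokinase gene, rose by 0.79 ± 0.14, and the glucose transporter gene Slc2a1 by 1.04 ± 0.20. Aldoc, Pfkp and Pfkm fell by 1.77 ± 0.40, 0.78 ± 0.17 and 0.62 ± 0.16, and Ldha, at -0.18 ± 0.18, was not called (adjusted p = 0.671). Prps2 and Ppat, which open purine synthesis, fell by 2.39 ± 0.22 and 1.06 ± 0.18, and Ctps rose by 0.39 ± 0.09, among 21 pentose phosphate and nucleotide synthesis genes with 1 rise, 2 falls and 18 not called (2 higher and 2 lower when adjusted over the list alone; list adjusted p = 0.128). Single arrays decided some of these results: glycolysis was called lower without DMSO 1 (adjusted p = 0.0203) and nucleotide synthesis without DMSO 2 or Torin1 2 (adjusted p = 0.0128 and 0.0178). Hk2, Prps2 and Ppat were called in every leave-out, but Slc2a1, Aldoc, Pfkp, Pfkm and Ctps each lost the call in at least 1 (adjusted p up to 0.0555 without DMSO 2, 0.102 without DMSO 3, 0.102 without DMSO 3, 0.119 without Torin1 1 and 0.127 without DMSO 1).

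Transcripts of the MTOR pathway itself showed no common direction. Mtor was at 6.92 ± 0.09 in DMSO and 6.99 ± 0.16 in Torin1 (SD, n = 3 each; adjusted p = 0.805). Eif4ebp1, a translation repressor regulated by MTOR, changed by 0.02 ± 0.11 (adjusted p = 0.948), and Rps6 by -0.12 ± 0.09 (adjusted p = 0.515), and neither was called. Of 38 pathway genes 6 rose, 3 fell and 29 were not called (7 higher and 3 lower when adjusted over the list alone; list adjusted p = 0.497). Rragd, which encodes a Rag GTPase, rose by 1.17 ± 0.13, Sgk1 by 1.29 ± 0.32 and Ddit4, an inhibitor of the pathway, by 0.91 ± 0.21. Depdc5, Lamtor2 and Mapkap1 fell by 0.85 ± 0.15, 0.76 ± 0.12 and 0.52 ± 0.10. Ddit4l, at -0.30 ± 0.19, was not called (adjusted p = 0.412) except without Torin1 3 (adjusted p = 0.0161). Its values in Torin1 samples 1, 2 and 3 were 3.865, 3.806 and 4.492, so the fall is larger without sample 3. Sgk1 was not called without DMSO 1, DMSO 2, DMSO 3 or Torin1 1 (adjusted p up to 0.133), Ddit4 only in the full set and without Torin1 1 (adjusted p otherwise up to 0.115), and Mapkap1 not without DMSO 1, DMSO 2 or DMSO 3 (adjusted p up to 0.0662).

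FOXO targets and insulin pathway feedback genes went both ways. Of 29 members 4 rose, 8 fell and 17 were not called (7 higher and 9 lower when adjusted over the list alone; list adjusted p = 0.821). Fbxo32, a ubiquitin ligase gene, Bcl6, Cited2 and Klf9 rose by 2.44 ± 0.27, 2.01 ± 0.17, 1.65 ± 0.17 and 0.78 ± 0.12. Cat (catalase), Irs1 (an insulin receptor substrate) and Foxo1 fell by 1.69 ± 0.27, 1.42 ± 0.15 and 1.01 ± 0.10. Irs2, at 0.79 ± 0.23, was not called (adjusted p = 0.0741), though it was without Torin1 2 or Torin1 3 (adjusted p = 0.0443 and 0.0300). Its values in Torin1 samples 1, 2 and 3 were 8.052, 7.836 and 8.767, so the rise is smaller without sample 3. Sesn3 fell by 0.71 ± 0.15 and kept its call only without Torin1 3 (adjusted p up to 0.0998 in the other leave-outs).

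Lysosomal genes included large falls and several rises, and the list was not called (adjusted p = 0.152). Of 40 members 7 rose, 10 fell and 23 were not called (10 higher and 14 lower when adjusted over the list alone). Naglu, Hexa, Ctsa and Scpep1, which encode lysosomal hydrolases, fell by 2.77 ± 0.15, 1.65 ± 0.26, 1.33 ± 0.10 and 1.22 ± 0.09. Ctsb, a cathepsin gene, rose by 0.88 ± 0.10. Tfe3, a transcription factor of lysosomal genes, rose by 0.49 ± 0.10 and was not called without DMSO 1, DMSO 2, Torin1 1 or Torin1 2 (adjusted p up to 0.0746). Without Torin1 2 the list was called lower (adjusted p = 0.0214). Of 34 autophagy genes 4 rose, 2 fell and 28 were not called (5 higher and 2 lower when adjusted over the list alone; list adjusted p = 0.556). Vmp1 rose by 1.79 ± 0.28 and Wipi1 fell by 0.72 ± 0.10. Smaller changes were called for Atg3 (0.50 ± 0.13), Rb1cc1 (0.46 ± 0.10), Sqstm1 (0.37 ± 0.09) and Gabarapl2 (-0.32 ± 0.08), each of which lost its call without DMSO 2, DMSO 3, Torin1 1 or Torin1 2 (adjusted p up to 0.164, 0.0955, 0.130 and 0.108). Atg3 was also lost without DMSO 1, and Gabarapl2 in every leave-out.

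Genes of translation moved in different directions by list. Transcripts of 59 cytosolic ribosomal proteins had a median of -0.14 (-0.26 without Torin1 3 and -0.0813 without Torin1 2), with 48 below 0, and camera called the list lower (adjusted p = 0.00467), but not with an estimated correlation (adjusted p = 0.817). The only called member, Rpl17, rose by 0.32 ± 0.07, against the list's direction, and 58 were not called (0 in either direction when adjusted over the list alone; 3 higher and 5 lower at an unadjusted p below 0.05 in limma). Rpl17 was called only in the full set and without Torin1 3 (adjusted p otherwise up to 0.115), and the list was not called without Torin1 1 or Torin1 2 (adjusted p = 0.101 and 0.137). Of 44 ribosome biogenesis genes 7 rose, 1 fell and 36 were not called, with the same counts when adjusted over the list alone and a median of 0.16 (0.27 without DMSO 1, the highest of the leave-outs). Nop2, Rrp12 and Nob1 rose by 0.66 ± 0.17, 0.60 ± 0.14 and 0.54 ± 0.11, and Polr1a, the largest subunit of RNA polymerase I, fell by 0.66 ± 0.14. In camera the list was called higher (adjusted p = 0.000406), and with an estimated correlation it was not called (adjusted p = 0.776). Each of these 4 members lost its call without DMSO 3 or Torin1 1, and also without DMSO 2 (Nop2, Rrp12, Nob1), Torin1 2 (Nop2, Rrp12), Torin1 3 (Nop2) or DMSO 1 (Polr1a), with adjusted p up to 0.150.

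Among aminoacyl-tRNA synthetase genes more rose than fell, with 5 of 18 called higher, 1 lower and 12 not called (7 higher and 1 lower when adjusted over the list alone) and a median of 0.23. Cars and Mars1 rose by 0.70 ± 0.12 and 0.67 ± 0.12 and Nars, Gars and Sars by 0.54 ± 0.11, 0.49 ± 0.11 and 0.46 ± 0.09, while Kars fell by 0.37 ± 0.08. The list was called higher by camera (adjusted p = 0.00312), but not with an estimated correlation (adjusted p = 0.737). Nars, Gars, Sars and Kars each lost the call without DMSO 2 or DMSO 3; so did Nars, Gars and Kars without DMSO 1, Sars and Kars without Torin1 1, and Gars, Sars and Kars without Torin1 2 (adjusted p up to 0.0982). Of 29 ATF4 targets, genes of amino acid synthesis and transport, 4 rose, 3 fell and 22 were not called (10 higher and 4 lower when adjusted over the list alone), with a median of 0.33. Atf4 itself, Cebpb, Slc3a2 and Slc7a11 rose by 0.91 ± 0.10, 1.36 ± 0.12, 1.18 ± 0.10 and 1.15 ± 0.19, the last not called when probe sets of a gene were averaged (adjusted p = 0.113). Slc38a1, Cbs and Aldh18a1 fell by 0.71 ± 0.09, 0.64 ± 0.11 and 0.63 ± 0.15, and Aldh18a1 was not called without DMSO 3 or any 1 Torin1 sample (adjusted p up to 0.0894). The list was called higher by camera (adjusted p = 0.0264) but not with an estimated correlation (adjusted p = 0.776), without DMSO 2 or Torin1 3 (adjusted p = 0.126 and 0.0694), among genes above the median level (adjusted p = 0.117) or with array weights (adjusted p = 0.0893).

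Among DNA replication and G1/S genes more fell than rose. Of 47 members 6 fell, 1 rose and 40 were not called (8 lower and 2 higher when adjusted over the list alone), with a median of -0.08 (-0.17 without DMSO 2, the lowest of the leave-outs). Rrm1, a ribonucleotide reductase gene, Chaf1b and Lig1 fell by 1.19 ± 0.23, 0.95 ± 0.20 and 0.80 ± 0.10, and Pcna rose by 0.63 ± 0.09. Camera called the list lower (adjusted p = 0.0198), and with an estimated correlation it was not called (adjusted p = 0.776). Nor was it called without DMSO 1, DMSO 3 or Torin1 1 (adjusted p = 0.0917, 0.0671 and 0.138) or among genes above the median level (adjusted p = 0.103). Rrm1 lost its call without DMSO 1 or DMSO 3 (adjusted p up to 0.0718) and Chaf1b without DMSO 1, DMSO 3 or Torin1 1 (adjusted p up to 0.0780). The cyclin gene Ccnd2, at -0.96 ± 0.26, was not called (adjusted p = 0.0604), though it was without Torin1 3 (adjusted p = 0.000257). Of 44 mitosis genes 4 fell, 1 rose and 39 were not called, also when adjusted over the list alone (list adjusted p = 0.915). Pimreg fell by 0.78 ± 0.10. Aurkb, Ccnb2 and Spc25 fell by 0.70 ± 0.12, 0.64 ± 0.13 and 0.61 ± 0.13 and Plk4 rose by 0.30 ± 0.07. None of these last 4 calls held without DMSO 3 (adjusted p = 0.0521, 0.0882, 0.0698 and 0.0977), and all but that of Aurkb ended without Torin1 1 (adjusted p = 0.0621, 0.0651 and 0.0799). Ccnb2 was also lost without DMSO 2, Spc25 without DMSO 1, and Plk4 in every leave-out.

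Cell death effectors, survival factors and p53 targets were not called as lists (adjusted p = 0.0562, 0.650 and 0.679). Of 24 death effectors 3 fell, 0 rose and 21 were not called, also when adjusted over the list alone, and the list was called lower without Torin1 1 or Torin1 2 (adjusted p = 0.0298 and 0.0306), with a pseudocount of 16 (adjusted p = 0.0483) and by fry (adjusted p = 0.0344). These were Bok, Tnfrsf10b and Diablo, which fell by 0.89 ± 0.09, 0.80 ± 0.11 and 0.65 ± 0.11, with Diablo not called without DMSO 3 (adjusted p = 0.0502). Of 14 survival factors Mcl1, an anti-apoptotic BCL2 family gene, rose by 0.80 ± 0.09 and 13 were not called, also when adjusted over the list alone. Of 20 p53 targets 3 rose, 4 fell and 13 were not called (4 higher and 5 lower when adjusted over the list alone). Beside Tnfrsf10b, the falls were Ccng1, Ei24 and Eda2r (-1.61 ± 0.18, -1.04 ± 0.14 and -0.89 ± 0.16), and the cyclin-dependent kinase inhibitor gene Cdkn1a rose by 0.68 ± 0.07. Btg2 and Mdm2 rose by 1.95 ± 0.45 and 0.38 ± 0.10 but were not called without DMSO 1, DMSO 2 or DMSO 3, nor Mdm2 without any 1 Torin1 sample (adjusted p up to 0.107 and 0.132). Eda2r lost its call without DMSO 1 (adjusted p = 0.0582).

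Stress lists were likewise not called. Of 24 unfolded protein response genes 5 rose, 3 fell and 16 were not called (6 higher and 4 lower when adjusted over the list alone; list adjusted p = 0.592). Dnajb9 and Ern1 rose by 1.00 ± 0.12 and 0.49 ± 0.07, and Derl3 and Sdf2l1 fell by 1.08 ± 0.16 and 0.89 ± 0.12. Herpud1, Ppp1r15a and Syvn1 rose by 0.93 ± 0.17, 0.87 ± 0.21 and 0.46 ± 0.10 and Sel1l fell by 0.68 ± 0.15, but none of these 4 was called without DMSO 3 (adjusted p = 0.0577, 0.120, 0.0829 and 0.0982). The last 3 were also lost without DMSO 1 or DMSO 2, and without Torin1 1 (Syvn1 and Sel1l) or Torin1 2 (Ppp1r15a and Syvn1). Of 17 heat shock chaperone genes Hspb8 rose by 0.68 ± 0.14, Hspb1 fell by 0.83 ± 0.11 and 15 were not called, also when adjusted over the list alone (list adjusted p = 0.679). Hspb8 was called only in the full set and without Torin1 3 (adjusted p otherwise up to 0.0842). Of 19 hypoxia response genes Hif1a rose by 0.80 ± 0.11, Fam162a fell by 0.98 ± 0.23 and 17 were not called, also when adjusted over the list alone (list adjusted p = 0.592). Without DMSO 1 that list was called lower (adjusted p = 0.00702), and Fam162a was not called without DMSO 1, DMSO 2 or DMSO 3 (adjusted p up to 0.121).

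Among SMAD targets 4 of 17 rose, 2 fell and 11 were not called, also when adjusted over the list alone, with a median of 0.27 (0.60 without Torin1 2, the highest of the leave-outs). Grem1 and Nog, both secreted antagonists of bone morphogenetic proteins, moved in opposite directions, by 2.27 ± 0.08 and -2.31 ± 0.19. Id1, Id4 and Skil rose by 2.16 ± 0.20, 1.27 ± 0.23 and 1.20 ± 0.08. Smad9 fell by 0.48 ± 0.12 and was called only in the full set and without DMSO 3 (adjusted p otherwise up to 0.113). Camera called the list higher (adjusted p = 0.00467), but not with an estimated correlation (adjusted p = 0.440). Some interferon response genes fell, with 6 of 21 called lower, 0 higher and 15 not called (7 lower when adjusted over the list alone) and a median of -0.11. Psmb9, an immunoproteasome subunit, Bst2, Stat2 and Xaf1 fell by 1.36 ± 0.16, 1.36 ± 0.11, 0.99 ± 0.14 and 0.57 ± 0.09. That list had a camera adjusted p of 0.00154 and an adjusted p of 0.125 with an estimated correlation. Extracellular matrix genes went both ways, with 7 of 25 higher, 6 lower and 12 not called (9 higher and 8 lower when adjusted over the list alone; list adjusted p = 0.665). Lox, a lysyl oxidase, and Timp3, a metalloproteinase inhibitor, rose by 1.99 ± 0.27 and 2.17 ± 0.39, and Sparc and Nid2 fell by 2.40 ± 0.32 and 2.16 ± 0.22. Timp3 was not called without DMSO 1 (adjusted p = 0.0517).

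Changes of oocyte transcripts were small and even. All 50 measured members had a change above 0, with a median of 0.20 and an SD over members of 0.0943. Of these 2 were called higher, 0 lower and 48 not called (0 in either direction when adjusted over the list alone; 23 higher and 0 lower at an unadjusted p below 0.05 in limma). Gdf9 and Bmp15, the oocyte's secreted growth factors, were at 0.12 ± 0.09 and 0.17 ± 0.09, and Zp3, of its extracellular coat, at 0.11 ± 0.08, none of them called (adjusted p = 0.512, 0.364 and 0.463). Figla and Dppa3 rose by 0.38 ± 0.09 and 0.31 ± 0.07, but Dppa3 was not called in any leave-out, and Figla not without DMSO 1, DMSO 3, Torin1 1 or Torin1 2 (adjusted p up to 0.118 and 0.116). Camera called the list higher (adjusted p = 3.41e-09), and it was not called with an estimated correlation (adjusted p = 0.487).

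Among markers of other ovarian cells, only the theca and stroma list was called. Of 19 theca and stroma genes 5 fell, 0 rose and 14 were not called (6 lower when adjusted over the list alone), with a median of -0.02 (-0.0560 without Torin1 3, the lowest of the leave-outs) and a mean of -0.38. Acta2, a smooth muscle actin gene, fell by 2.87 ± 0.12. Ptch1 and Gli1, both targets of hedgehog signalling, fell by 1.53 ± 0.19 and 1.25 ± 0.23, and Pdgfra and Cnn1 by 0.82 ± 0.08 and 0.60 ± 0.11. Camera called the list lower (adjusted p = 0.0152), but not with an estimated correlation (adjusted p = 0.440) or without DMSO 2 (adjusted p = 0.0639), where Gli1 was not called either (adjusted p = 0.0551). Among 16 endothelial genes Cdh5 rose by 2.33 ± 0.37, Sox18 and Egfl7 fell by 0.53 ± 0.10 and 0.40 ± 0.07, and 13 were not called (2 higher and 2 lower when adjusted over the list alone; list adjusted p = 0.376). Sox18 and Egfl7 were not called without DMSO 2 or DMSO 3 (adjusted p up to 0.0694 and 0.0538). Among 19 leukocyte genes Cd68 rose by 0.54 ± 0.11 and 18 were not called, also when adjusted over the list alone (list adjusted p = 0.252), and Cd68 was not called without any 1 DMSO sample or Torin1 1 (adjusted p up to 0.0681). Of 11 surface epithelium genes 0 were called over all genes or when adjusted over the list alone (1 higher at an unadjusted p below 0.05 in limma; list adjusted p = 0.315). The smallest p belonged to Krt7 and Bnc1, at 0.27 ± 0.11 and 0.25 ± 0.13 (adjusted p = 0.190 and 0.320).

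**Figure D3:**
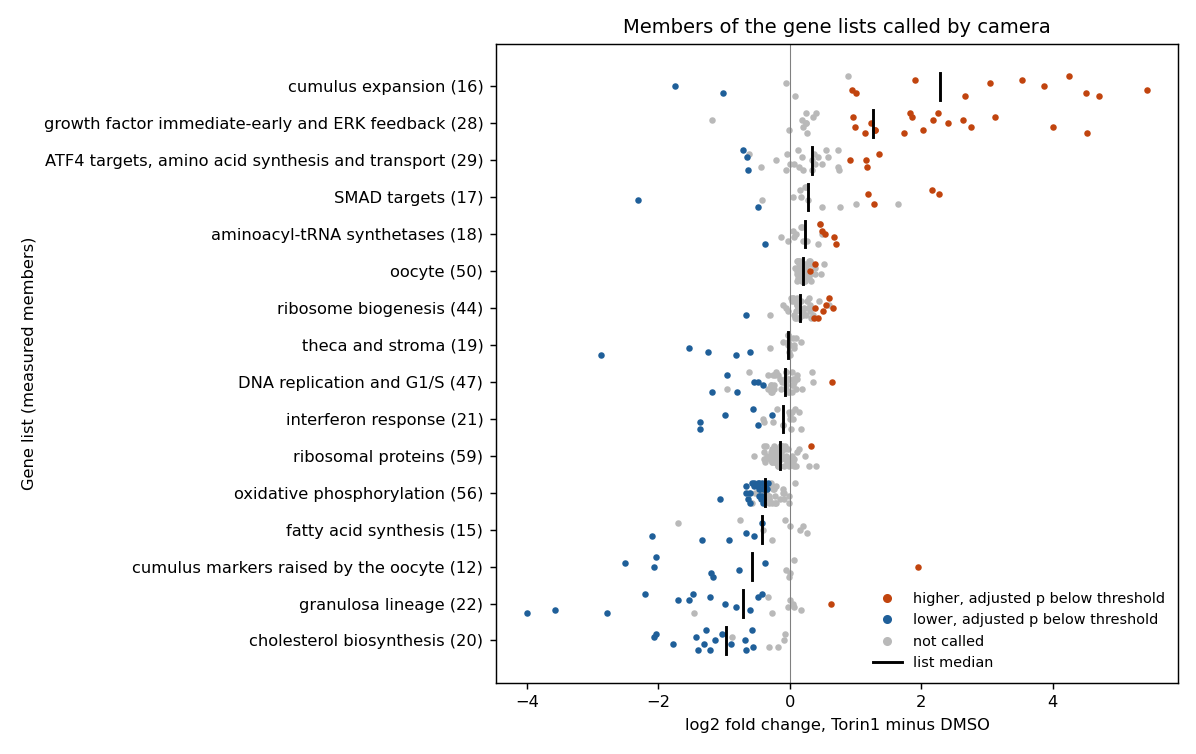
Log2 fold change, Torin1 minus DMSO (x axis), of each measured member of the 16 gene lists called by camera (y axis, number of measured members in brackets), with black bars for list medians and colour for members called higher or lower at an adjusted p below 0.05. Cumulus expansion (median 2.28) and immediate-early genes (1.26) lie farthest to the right and cholesterol biosynthesis (-0.96) farthest to the left.

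In all, camera called 16 of 34 lists, 7 higher and 9 lower. With an estimated correlation 0 lists were called (lowest adjusted p = 0.101; 7 at an unadjusted p below 0.05), and fry called 11, of which 10 were among the 16. Other ways of splitting the 6 arrays into 3 and 3 also gave 4 to 12 lists called by camera with the preset correlation. Each of these splits mixes DMSO and Torin1 arrays unequally, so part of the Torin1 change stays between its groups. Their list counts therefore give no chance level for camera. Median, mean and camera direction differed in sign for the cell survival, mural granulosa, mitosis, p53 and FOXO lists, none of which was called. Level-matched lists did not always go with camera. Medians of the called DNA replication and theca lists lay at percentiles 5.54 and 22.2, within the central 95% of matched lists. Those of the glycolysis, endothelial and surface epithelium lists, not called by camera, lay outside it (percentiles 0.07, 97.8 and 98.8).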

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

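Of the tests below, the slope test of a weaker response in Torin1 sample 3, as a part of the difference, was written before its values were seen. So were the splits and the level-matched lists. All other tests of the oocyte, oxidative phosphorylation and sample 3 patterns were chosen only after the results were seen. These include the test of a weaker response as the whole difference.

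Some probe sets that no gene-level result covers were called as well, each adjusted over its own group. Of the 16010 absent from the gene table, 42 were called higher and 24 lower with Torin1. Of the 1814 naming several genes, 32 were called higher and 86 lower. Both shares lay below the 12.1% called among genes tested. The genes of these probe sets were not analysed here.

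The real grouping gave the most changed genes of the 10 possible splits of the arrays (1 of 10 as large; highest other split 0 genes, or 1638 against 5328 at an unadjusted p below 0.05 in limma). For gene lists it was also 1 of 10, with 16 lists against at most 12. With so few splits no share under 0.05 can be reached. The other splits each mix both treatments unequally, so part of the Torin1 change stays between their groups and the rest widens their spread. Their counts of genes and lists thus do not show what would be called without a treatment effect. Calls by camera with its preset correlation stay weak evidence, because 0 lists were called with an estimated correlation. Fry, however, called 10 of the 16 lists, and the estimated correlations themselves rest on only 6 arrays.

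Changes in the oocyte list lay evenly above 0, with a median of 0.20. A shift that depends on signal level did not account for it, because the median lay at percentile 99.97 of level-matched lists. The SD of the members' changes was 0.0943 against 0.332 to 0.813 (median 0.517) in matched lists, but this only restates their evenness, which transcripts of an unresponsive cell would show under any offset. A lower share of cumulus RNA in the sample and greater stability of oocyte RNA stay open.

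Oxidative phosphorylation genes had a median of -0.38, at percentile 0 of level-matched lists, which argues against a shift that depends on signal level. A loss of short abundant transcripts in amplification could lower ribosomal protein genes equally. Their median lay 0.231 above that of the list (95% bootstrap interval over genes 0.158 to 0.295). The interval resamples genes and leaves out the spread between arrays. In the leave-outs, medians ran from -0.26 to -0.0813 for ribosomal proteins and from -0.42 to -0.33 for the list. These ranges did not overlap, so an equal loss was not seen. A loss of unequal size stays open, since 48 of 59 ribosomal protein genes lay below 0. Dim members, such as Rpl30 and Rpl37 at 2.84 and 3.31 in DMSO, may also draw their median towards 0. Mitochondrial ribosomal protein genes also lay below 0 in the median (-0.18), but 0.197 above the list (interval over genes 0.128 to 0.302). An equal fall of all nuclear-encoded mitochondrial genes was thus not seen in the group means, but this interval does not cover the spread between arrays. A shared fall of unequal size stays open. Lower synthesis of these transcripts stays open, as does a lower share of cumulus RNA, which was not tested for this list. Respiratory capacity was not measured.

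Torin1 sample 3 lay apart from samples 1 and 2. A second array of sample 2 stays open: the SD of log2 differences between samples 2 and 3, 0.350 against 0.204 to 0.240 in pairs without sample 3, only restates the pattern, and a poor repeat array would give it too. A batch shared by the samples numbered 3 stays open. Their deviations from the group means correlated at -0.148, so no sharing was seen, but other pairs ran from -0.300 to 0.311. Deviations within a group also sum to 0, which ties these values together. A weaker response in sample 3 may be part of the difference, since its slope was 0.899 times that of sample 2 in 195 genes picked on sample 1 (0.853 to 0.944), though deviations shared by samples 1 and 2 would give this too. It was not the whole, because only 16.6% (65 of 391; 13.1 to 20.7%) of the genes at least 2-fold apart lay between the groups.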

How the results depend on the processing

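Only the alternative with no pseudocount was chosen after the results were seen. The 185 called named genes kept direction and call in 2987 of 3323 comparisons, lost the call in 336 and reversed in 0, and the 12 named genes not called gained a call in 14 comparisons. The 185 called named genes include Dusp18, Gsto1, Gstm1, Mrps18b and Mrpl42, from the dual-specificity phosphatase, glutathione transferase and mitochondrial ribosomal protein families. A pseudocount of 16 ended 23 calls (Aldoc, Pfkp, Pfkm, Nop2, Rrp12, Atg3, Sgk1, Ddit4, Chaf1b, Btg2, Hspb8, Fam162a, Slc38a3, Sfrp2, Inhbb, Kitl, Timp3, Nr0b1, Aldh18a1, Smad9, Ppp1r15a, Mrps18b, Mrpl42), centring on the median 14 (Ctps, Gars, Nop2, Rrp12, Atg3, Rb1cc1, Sgk1, Dppa3, Nr0b1, Sqstm1, Mdm2, Plk4, Ppp1r15a, Mrps18b), and Torin1 samples 2 and 3 as 1 sample 13 (Ctps, Nop2, Ddit4, Figla, Dppa3, Aldh18a1, Smad9, Pfkm, Sqstm1, Gabarapl2, Mdm2, Plk4, Mrps18b). Each of these genes also lost its call in at least 1 leave-out. The number of changed genes fell to 1172 (489 higher, 683 lower) at an adjusted p below 0.01, as a stricter limit must, and the genes changed at least 2-fold fell to 466 with a pseudocount of 16, which shrinks changes of dim genes. Leaving out 1 array, and so testing fewer samples, gave 1518 to 3083 changed genes (655 to 1389 higher, 844 to 1694 lower), and medians of 0.25 to 0.35 for ATF4 targets, -0.26 to -0.0813 for ribosomal proteins, -0.17 to -0.0612 for DNA replication, 0.22 to 0.60 for SMAD targets, 0.11 to 0.27 for ribosome biogenesis and -0.0560 to -0.0241 for theca and stroma. With a replicate block on the sample number 1565 genes changed (657 higher, 908 lower), and 46 of the called named genes lost the call. The labels do not pair the samples. Same-numbered samples correlated at -0.207, -0.300 and -0.148, and no sample correlated best with its own number (differently numbered samples reached 0.311). With an estimated correlation 0 lists were called, at unchanged medians: cholesterol -0.96, fatty acid -0.42, ATF4 0.33, synthetases 0.23, ribosomal proteins -0.14, biogenesis 0.16, DNA replication -0.0793, oxidative phosphorylation -0.38, immediate-early 1.26, SMAD 0.27, expansion 2.28, cumulus markers -0.58, granulosa -0.71, oocyte 0.20, theca -0.0235 and interferon -0.11. Fry did not call ATF4 (0.33), synthetases (0.23), ribosomal proteins (-0.14), biogenesis (0.16), DNA replication (-0.0793) and oocyte (0.20). Among genes above the median level ATF4 (0.27) and DNA replication (-0.10) were not called, nor was ATF4 with array weights (0.26). For the block, the estimated correlation, fry and these last alternatives, the cause was not tested. The stricter limit on p was not applied to lists, and apart from it, fry and the estimated correlation, each alternative called 14 to 18 lists. No background values are in the sources used here, so the limit that weak signal sets on dim genes was not measured.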

Other observations

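The families below were chosen only after the results were seen, and the genes named from them were picked as examples by their values, so no test of a family as a whole is given. Krüppel-like factor genes, which encode zinc finger transcription factors, rose more often than they fell: of 17 members 7 rose, 1 fell and 9 were not called, with a median of 0.41. Klf5 and Klf4 rose by 3.05 ± 0.30 and 2.76 ± 0.24, and Klf8 fell by 1.39 ± 0.15. Dual-specificity phosphatase genes, many of which encode enzymes that inactivate MAP kinases, rose in 8 and fell in 1 of 24, with a median of 0.21, Dusp6 at 2.18 ± 0.13. Sox9, which encodes a transcription factor of testicular Sertoli cells, rose by 2.80 ± 0.20.

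Some members of transport and metabolic families fell, though not every family was lower as a whole. Of 5 sodium pump subunit genes 3 fell, among them Atp1b2 and Atp1b1 by 3.91 ± 0.27 and 2.57 ± 0.44, and Atp1b3 by 0.54 ± 0.09. Of 11 Slc38 amino acid transporter genes 4 fell and 0 rose, Slc38a5 and Slc38a4 the most, by 3.36 ± 0.21 and 2.98 ± 0.23, beside Slc38a3 and Slc38a1. Of 21 aldehyde dehydrogenase genes 2 rose and 6 fell, with Aldh1a3, which forms retinoic acid, up by 3.55 ± 0.15 and Aldh3a2 down by 1.25 ± 0.12. Of 38 proteasome subunit genes 4 fell and 0 rose, and these included the immunoproteasome subunits Psmb10 (-1.60 ± 0.12), Psmb9 (-1.36 ± 0.16) and Psmb8 (-0.49 ± 0.09), beside Psma2. Mitochondrial ribosomal protein genes fell in 10 and rose in 1 of 71, with a median of -0.18. Of 87 potassium channel genes 12 fell, Kcnj3 among them by 1.77 ± 0.08, and 2 rose, Kcnk5 and Kcnk10, by 3.39 ± 0.12 and 2.43 ± 0.26. Medians were 0.00265 for potassium channel, -0.06 for Slc38, -0.54 for sodium pump, -0.13 for aldehyde dehydrogenase and -0.13 for proteasome genes. Over all genes tested, 12.1% were called.

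In Torin1 sample 3, 391 genes were at least 2-fold from samples 1 and 2, with 208 higher and 183 lower. Npr3, a natriuretic peptide receptor gene, and the growth factor gene Alkal2 were higher by 3.63 and 3.27, and Fbn2, Tgfbi and Ccn1, which encode proteins of the extracellular matrix, were higher by 3.11, 3.09 and 2.32. Ace, Srpx2 and Tns4 were lower, at -3.00, -2.79 and -2.39. These values rest on 1 array and carry no test.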
